A study of Mus musculus with 54 samples.

How the data were processed

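Total RNA from LLC (Lewis lung carcinoma) tumours, grown in male C57BL/6 mice of 4 host ages, was profiled on Illumina Mouse WG-6 bead arrays with 1 tumour per array. The deposited table of raw values holds, per the file headers, an average bead signal for each probe, an intensity that is neither background-subtracted nor normalized, and a detection p-value for each probe and array. Per the file headers this detection p-value was given without further adjustment, and it moves in steps set by the negative control probes. The deposited processed table holds intensity values on a linear scale that the authors, by the design text of the series, corrected through housekeeping genes and quantile normalized. The values show 1 shared distribution over the 54 arrays, and the housekeeping step could not be checked from them. Each processed column ranked the probes as 1 raw array of the same age group did (lowest rank correlation of a best match 0.9997, highest of a second match 0.937). Raw arrays carry a number and an age group and were assigned to groups by that name. Adolescent, young adult and middle-aged arrays are named in the text by their order of array number within the group, and old arrays by the number itself. The design text counts more tumours than there are arrays (20 adolescent, 20 old, 10 of each other age), and the rest are not analysed here.

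Raw signals were processed with neqc in limma 3.58.1 under R 4.3.3. This estimates the background from the detection p, adds an offset of 16, quantile normalizes the arrays and takes log2. Of 45281 probes, 17668 were kept because their detection p was under 0.01 in at least 7 arrays, 7 being the size of the smallest group. Age group was the only factor of the limma model. A moderated F over the 4 groups and 6 pairwise contrasts were tested, each with Benjamini-Hochberg adjustment over the kept probes, and a probe was called at an adjusted p under 0.05. Signals on arrays have no counting depth, so the number of arrays limits the precision. Log2 differences are given with the standard error (SE) of the fit, and group values as mean ± SD over arrays.

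Before the data were examined, 48 gene lists were written, and 44 of them had at least 4 measured genes. The lists for Y-linked genes, B cells, lymphatic endothelium, and keratinocytes and skin had fewer and were not tested. Each list was tested with camera in limma (inter-gene correlation preset at 0.01, two-sided) on 11992 genes, with the brightest kept probe for each gene, and adjusted over the 44 lists. Camera with an estimated correlation and fry, a rotation test of the list alone, were set as alternatives at the same time. A permutation test of the mean of each list per array was added after random regroupings of the arrays were found to give many lists under the preset correlation. It is exact where a group has fewer than 10 arrays and uses 100000 draws elsewhere. Every list was therefore put through 4 tests, and the report gives the outcomes for the lists it describes in detail.

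Named genes follow a rule set with the lists. For old minus adolescent it takes the 10 highest and 10 lowest log2 differences among called probes, and for the other contrasts up to 5 and 5. It adds the 10 lowest F p, up to 4 members of each list called by camera, and 13 genes that are always given. Predicted genes known only by a clone or locus number were left out of the ranking, 1003 of the called probes in old minus adolescent among them. Symbols were updated with the reference table of mouse genes (assembly GRCm38.p6, used for names only): 27740 probe symbols were current, 8037 were replaced through a synonym and 9504 were kept as in the file. Genome coordinates were not used here. A few genes that the naming rules picked are not reported here. Where a probe was not above background on any array of a group, the change is given as a lower bound on the fold.

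The alternatives were other normalizations, the processed values of the authors, other filters, array weights, no moderation, 2 groups at a time, other list tests, and leaving out each array in turn. The files name no slides, so a block for slides, intended beforehand, could not be run. Several choices were made after the arrays had been seen. Fits without 2 old arrays (numbers 95 and 96, which carried lung transcripts) and without 9 old arrays (those 2 and the others that detected fewer probes than any array of the other ages, leaving 10 old arrays) are such choices. So are a random block for each run of array numbers, 2 added lists (lung epithelium and liver), and the repeat of the naming rule without the 9 arrays. Rules of 2 later tests were also changed once their outcome was known, and the closing part gives each version. A test of host age for the arrays with few probes was replaced, because the pattern itself fixed its outcome.

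The procedure was tested on simulated data built from the means and spreads of the 17668 probes. The simulated noise was normal and independent between probes and arrays, with no runs and no outlying arrays. For old minus adolescent it recovered 97 of 100 probes changed by 1 on the log2 scale and 53 of 100 changed by 0.5, with 7 false calls. For middle-aged minus young adult it recovered 75 and 30 of 100, with 7 false calls. Random regroupings of the real arrays called up to 1929 probes for old minus adolescent, so these false calls are no guide to the real data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.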

Results

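Tumours from 54 mice were compared: 18 adolescent (68 days old), 10 young adult (143 days), 7 middle-aged (551 days) and 19 old (736 days). Adolescent arrays detected 14579 to 17142 probes, young adult arrays 14577 to 16553, middle-aged arrays 14598 to 16450 and old arrays 11105 to 15694. Median raw signals ran from 89.2 to 303 over the groups. In 8 old arrays fewer than 14577 probes were detected, and old arrays 95 and 96 carried transcripts of lung epithelium such as Scgb1a1, the club cell secretory protein, and Sftpc, a surfactant protein. Scgb1a1 reached 14.53 and 14.58 (log2) in these arrays and at most 5.19 in the other 52. Sftpc reached 14.12 and 14.41 and at most 5.24. The arrays of each age form their own runs of numbers, so a batch that follows the numbers cannot be told apart from age in any comparison. Young adult and middle-aged arrays form 1 run each, and only adolescent and old arrays show how runs of 1 age differ. The random block for the number runs has only 7 runs to draw on, so its counts cannot settle this. Between the 2 runs of adolescent arrays (9 against 9), 3299 probes differed in limma.

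**Figure D1:**
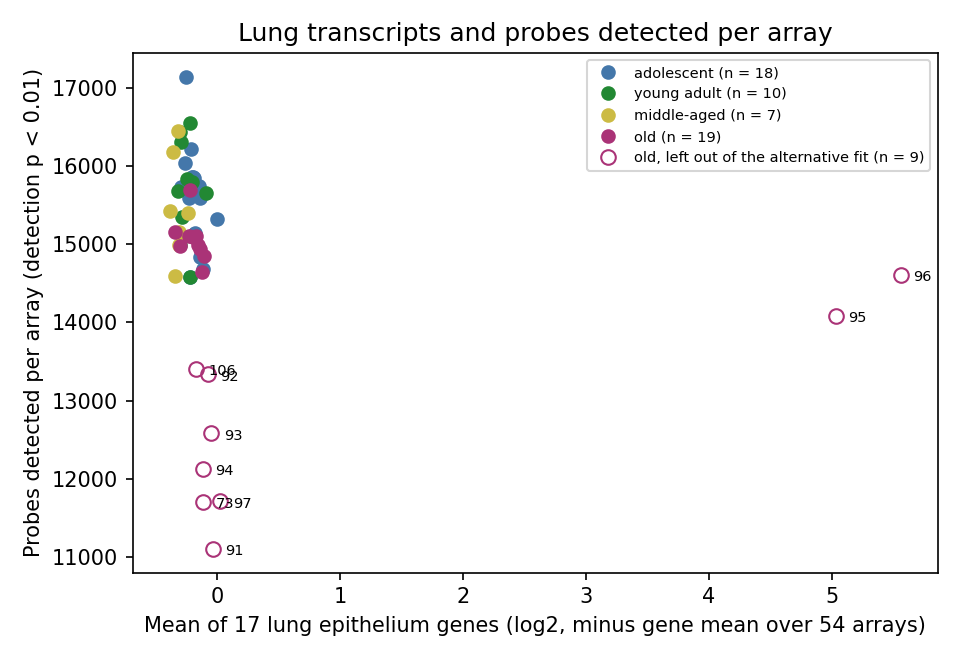
Each point is 1 tumour array, with the mean of 17 lung epithelium genes on the x axis (log2, relative to the mean over 54 arrays) and the number of probes detected on the y axis. Open circles, with their array numbers, are the 9 old arrays left out of the alternative fit; arrays 95 and 96 lie apart to the right, and the other 7 lie below 14577 probes.

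The first comparison asked which transcripts in the tumour differed with the age of the host over all 4 groups. Tcf20, a transcriptional coregulator, had the lowest F p: it averaged 6.52 ± 0.22 (SD, n = 18) in adolescent, 7.74 ± 0.64 (n = 10) in young adult, 7.84 ± 0.37 (n = 7) in middle-aged and 5.18 ± 0.30 (n = 19) in old tumours. Bmx, a Tec family tyrosine kinase, was also lowest in old tumours, with means of 6.87, 7.75, 7.56 and 5.14. Snrnp70, a component of the U1 spliceosomal particle, and Rtcb, the tRNA ligase, were also lowest in old tumours. Other names of lowest F p were Igdcc4, Robo1, Olfr536, Olfr873 and Sorbs3, whose probes were detected in 0 of 19 old arrays. In all, 10403 of 17668 probes were called by the moderated F. Among them 857 (8.24%) had group means that rose or fell steadily with age, and in 5386 (51.8%) the adolescent mean lay between the old mean and those of the other ages. The 4 means can take 24 orders, and only the steady rise and the steady fall count as steady. The 8.24% is therefore no more than an even spread over the orders would give. Without the 9 old arrays 9671 probes were called, and with a random block for the number runs 1690 were.

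Old minus adolescent compared the largest groups over the widest span of ages. Interferon-stimulated genes, which cells switch on in response to interferon, were higher in old tumours: 17 of 25 measured members rose and 1 fell, and 17 and 1 did when adjusted over the list alone. Usp18, a brake on interferon signalling, rose by 1.22 on the log2 scale (SE 0.239, adjusted p = 7.34e-05), Oasl2 by 1.01 (SE 0.192) and Zbp1, a sensor of nucleic acids, by 0.96 (SE 0.130). The mean of the list was 0.62 higher (camera adjusted p = 3.06e-05, but adjusted p = 0.979 with an estimated correlation). It was 0.40 higher without background correction, 0.41 in the processed values of the authors and 0.35 under median scaling, where the median over all probes was -0.28. Fry gave an adjusted p = 0.0012 and the permutation test 0.0057, and with a random block for the number runs fry gave p = 0.0286 (adjusted 0.63). Without the 9 old arrays the mean difference was 0.59 with 16 members higher, and the permutation test no longer passed (adjusted p = 0.073).

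Cell cycle genes were lower in old tumours: 17 of 30 measured members fell, 19 when adjusted over the list alone, and 0 rose. Ccnb1, the mitotic cyclin B1, fell by 1.01 (SE 0.190, adjusted p = 4.46e-05), Aurkb by 0.66 (SE 0.163), Bub1b, a spindle checkpoint kinase, by 0.52 (SE 0.131) and Mcm6, part of the replicative helicase, by 0.48 (SE 0.118). The proliferation marker Mki67 differed by -0.19 (SE 0.106, adjusted p = 0.159). The mean of the list fell by 0.34 (camera adjusted p = 4.16e-04, but adjusted p = 0.979 with an estimated correlation; fry 0.0376, permutation 0.0057). Under median scaling the mean fell by 0.58. With a random block for the number runs fry gave p = 0.115 (adjusted 0.841). Lung transcripts and low detection sat in the same group, and without the 9 old arrays 5 members fell, the mean difference was -0.19 and the permutation test gave an adjusted p = 0.123.

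**Figure D2:**
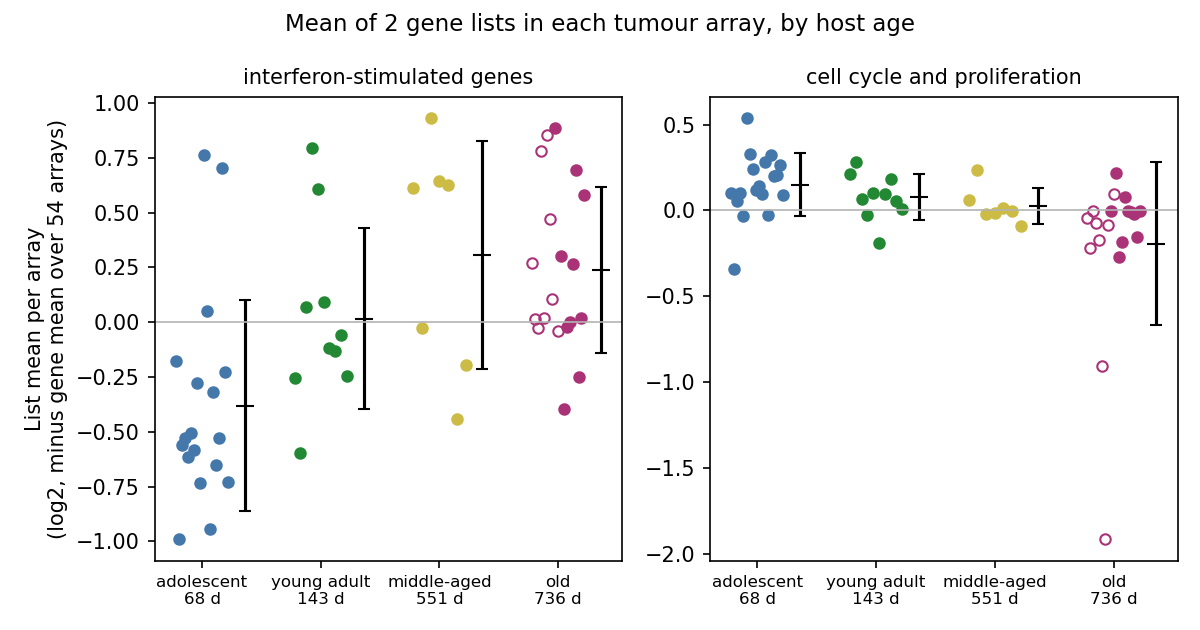
Each point is the mean of 1 gene list in 1 tumour array (log2, relative to the mean over 54 arrays), by host age in days; the cross bars are group mean and SD, and open circles are the 9 old arrays left out of the alternative fit. Interferon-stimulated genes averaged -0.38 in adolescent and 0.24 in old tumours. The 2 lowest cell cycle means are those of old arrays 95 (-0.91) and 96 (-1.91), which carried lung transcripts.

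Among single genes in old minus adolescent, the highest differences were those of Fhl1, Inmt, Myo5c, Ism1, Cmpk2, Esyt3, Slfn1, Slc12a1, Cd8b1 and Usp18. Cmpk2, a mitochondrial nucleotide kinase, rose by 1.34 (SE 0.235), Cd8b1, the beta chain of the T cell coreceptor CD8, by 1.22 (SE 0.252), and Slc12a1, an ion cotransporter, by 1.23 (SE 0.120). Inmt and Fhl1 rose by 1.57 each, and their adjusted p without the 9 old arrays was 0.264 and 0.494. The lowest differences were those of Mup2, Bmx, Hnrnpa0, Mtch1, Atf7, Rhbdl1, Arf5, Mup1, Mlf2 and mt-Nd4l. Mup2, a major urinary protein, averaged 7.68 ± 1.89 in adolescent and 5.44 ± 1.61 in old tumours, and Bmx fell by 1.73 (SE 0.142, adjusted p = 2.69e-13). mt-Nd4l, a mitochondrial subunit of complex I, was detected in 0 of 19 old arrays and was at least 1.23-fold lower there. Cd274, the ligand PD-L1, rose by 0.68 (SE 0.148, adjusted p = 2.98e-04). Tgfb1, the growth factor TGF-beta 1, fell by 0.60 (SE 0.128, adjusted p = 1.98e-04), and without the 9 old arrays its difference was -0.28 (adjusted p = 0.0508). Foxp3, the factor of regulatory T cells, rose by 0.35 and Cd68, a macrophage marker, fell by 0.42; without the 9 old arrays their adjusted p was 0.677 and 0.855. Tgfbr2 differed by 0.11 (adjusted p = 0.32) and Vegfa by 0.56 (adjusted p = 0.0702). Kdr, Cd8a, Cd4, Pdcd1 and Cdkn2a did not pass the detection filter.

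In old minus adolescent, 2864 probes were higher and 4099 lower (522 and 5815 under median scaling). Without the 9 old arrays 1905 were higher and 1916 lower, and 2460 of these 3821 had been called with the same sign in all 54 arrays. The naming rule applied again to that fit gave, among the highest, the interferon-inducible Gbp2, Igtp and Ifi205, the MHC class II chain H2-Ab1 and the scavenger receptor Scara5. Scara5 rose by 1.44, Gbp2 by 1.44 and Igtp by 1.17. The other highest names were Fn1, Tmem168, Rgs1, Cnot1 and Ncoa4. The lowest were Mup2, Bmx, Hykk, Mup1, Mup3, Serpina1e, Mast4, Hbb-b1, Agap3 and Lrch3. With a random block for the number runs 896 probes were called.

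**Figure D3:**
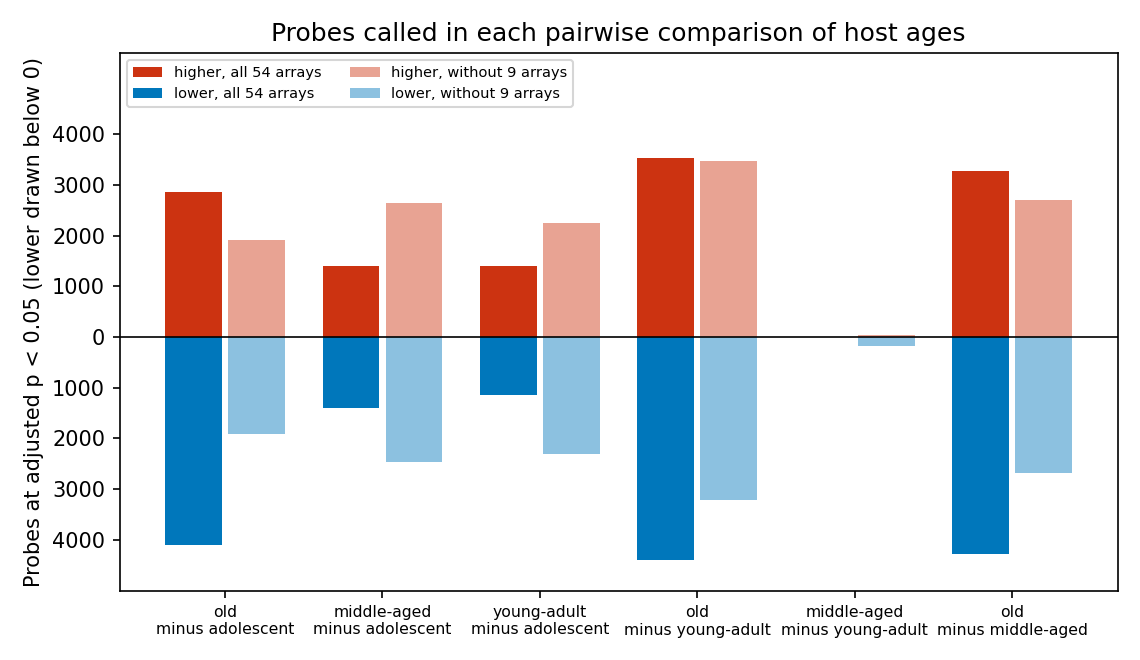
Bars give the number of probes higher (red) or lower (blue, drawn below 0) at an adjusted p under 0.05 in each pairwise comparison, in all 54 arrays (dark) and without the 9 old arrays (pale). Middle-aged minus young adult has the smallest counts, 6 and 212.

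Middle-aged minus adolescent showed the largest rise in Bst2, the antiviral membrane protein tetherin, at 2.78 (SE 0.355, adjusted p = 3.56e-07, n = 7 and 18). Bax, a mediator of apoptosis, rose by 2.35 (SE 0.280), and Npm3, Trappc3 and Ppp3r1 rose by 2.04, 1.97 and 1.97. Hykk fell by 1.99, the transporter Slco4a1 by 1.85, the cytoskeletal actin Actb by 1.78, Ngef by 1.53 and Prf1, the pore-forming perforin of cytotoxic cells, by 1.53. Of 25 interferon-stimulated genes 9 rose and 1 fell (15 and 1 adjusted over the list alone), with Ifit3 up by 1.33, Stat2 up by 0.84 and the GTPase Irgm1 down at -0.83. The mean of this list was 0.69 higher (camera adjusted p = 4.46e-06, but adjusted p = 0.772 with an estimated correlation; fry 0.0214; exact permutation 0.0279).

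Immediate early genes, the first to respond to growth and stress signals, had 3 of 17 members higher in middle-aged than in adolescent tumours (7 adjusted over the list alone): Fosb rose by 1.85, Egr1 by 0.95 and Klf6 by 0.50. Ier3 differed by 0.84 (adjusted p = 0.05). Their mean was 0.56 higher (camera adjusted p = 9.22e-04, but adjusted p = 0.772 with an estimated correlation; fry 0.0205; exact permutation 0.0279). Complement genes had 2 of 11 members higher (2 adjusted over the list alone), C1s1 by 1.04 and C1qa by 0.82, while C4a and C4b differed by 1.35 and 1.20 without passing. The complement mean was 0.58 higher (camera adjusted p = 0.0438, but adjusted p = 0.772 with an estimated correlation; fry 0.041; exact permutation 0.0279). For MHC class II presentation 1 of 10 members rose (3 adjusted over the list alone), Ctss by 0.69, and H2-Aa, Cd74 and H2-DMb1 differed by 1.01, 1.18 and 0.79 without passing. Cytosolic ribosomal proteins had 10 of 38 members lower and 3 higher (11 and 3 adjusted over the list alone), with Rpl23 at -0.63, Rpl38 at -0.48 and Rpl37 at -0.42. Camera gave adjusted p of 0.0438 and 0.0402 for MHC class II and the ribosomal proteins, but adjusted p = 0.905 for both with an estimated correlation. Fry gave adjusted p of 0.201 and 0.041, and the exact permutation test 0.207 and 0.0536. The camera calls of complement, MHC class II and the ribosomal proteins were each lost on leaving out 1 array, which held for 9, 12 and 4 of the 54 arrays. Tgfbr2 rose by 0.49 (adjusted p = 0.0026). In total 1403 probes were higher and 1395 lower (4171 and 208 under median scaling). Without the 9 old arrays the pooled spread was smaller and 5093 probes were called, while with a random block for the number runs 0 were called in limma (1011 at an unadjusted p under 0.05).

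Young adult minus adolescent had higher Hbb-b1, the beta globin, by 1.95 (SE 0.601, adjusted p = 0.0212, n = 10 and 18), Bst2 by 1.74 (SE 0.314), Bax by 1.67 (SE 0.248) and the neutrophil chemokine Cxcl2 by 1.55 (SE 0.501). Lrp5, a Wnt coreceptor, was detected in 0 of 10 young adult arrays and was at least 1.79-fold lower there. Slco4a1 fell by 1.56, Sspn by 1.30, the ectonucleotidase Entpd2 by 1.26 and Srpx2 by 1.19. Of 25 interferon-stimulated genes 4 rose (8 and 1 lower adjusted over the list alone), among them Rsad2 by 1.28, Ifit3 by 0.85 and Oasl2 by 0.67. Of 17 immediate early genes 2 rose (7 adjusted over the list alone), Fosb by 1.49 and Egr1 by 0.75, while Egr3 and Klf6 differed by 0.43 and 0.28 without passing. The list means were 0.40 and 0.42 higher (camera adjusted p = 0.0068 and 0.0113, but adjusted p = 0.923 and 0.684 with an estimated correlation). Fry gave adjusted p of 0.157 and 0.0456, and the permutation test 0.115 and 0.048. In total 1399 probes were higher and 1154 lower (1174 and 125 under median scaling). Without the 9 old arrays 4552 were called, and with a random block for the number runs 0 in limma (649 at an unadjusted p under 0.05).

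Old minus young adult showed higher Wfdc2, a secreted epithelial protein, by 2.77 (SE 0.642), Inmt by 1.73 and the growth factor Igf2 by 1.68 (SE 0.283). Wfdc2 was 14.61 and 14.63 in old arrays 95 and 96 and at most 8.80 in the other old arrays, and Inmt had an adjusted p = 0.173 without the 9 old arrays. Klf10, a TGF-beta inducible factor, and Mlxipl were not detected in young adult tumours and were at least 1.86-fold and 1.42-fold higher in old ones. Hnrnpa0 fell by 2.78 and Bmx fell by 2.61, and Tcf20, detected in 0 of 19 old arrays, was at least 2.89-fold lower. Hbb-b1 fell by 2.34 and Hmox1, the heme oxygenase, by 2.30 (SE 0.423). Tgfb1 fell by 0.92 (SE 0.152), and by 0.59 without the 9 old arrays. Camera called 0 of 44 lists, also with an estimated correlation, while fry called 8. The oxidative stress response list, with 7 of 20 members lower and 2 higher (the same counts adjusted over the list alone), averaged -0.30 (camera adjusted p = 0.462, and 0.94 with an estimated correlation; fry 0.005, permutation 0.0282). The platelet and megakaryocyte list averaged -0.99 with 2 of 4 members lower (camera adjusted p = 0.462, and 0.94 with an estimated correlation; fry 0.0062), and its permutation adjusted p was 0.0282 and, without the 9 old arrays, 0.0024. In total 3534 probes were higher and 4397 lower (583 and 7118 under median scaling), 6687 were called without the 9 old arrays, and 1333 were called with a random block for the number runs.

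Old minus middle-aged gave higher Klf10, by at least 1.79-fold, Wfdc2, by at least 3.98-fold, Fhl1 by 2.10, the ribosome biogenesis factor Tsr3 by 1.89 (SE 0.250) and the calcium pump Atp2a3 by 1.85 (SE 0.539). Fhl1 had an adjusted p = 0.239 without the 9 old arrays. Hnrnpa0 fell by 3.03, Bst2 by 2.59 (SE 0.352), Bmx by 2.42 and Fxr2 by 2.41, and Tcf20 was at least 3.09-fold lower. Vegfa, the vascular growth factor, rose by 1.36 (SE 0.337, adjusted p = 0.0011). Cd274 rose by 0.62 (adjusted p = 0.0096), and its difference was -0.072 under median scaling, where the median over all probes was -0.64. Camera called 0 of 44 lists, also with an estimated correlation, and fry called 4; for the 2 lists that follow, camera gave an adjusted p = 0.169 each, and 0.959 with an estimated correlation. Of 38 cytosolic ribosomal proteins 15 were higher and 4 lower (16 and 4 adjusted over the list alone; fry adjusted p = 0.0299, exact permutation 0.208). Of 17 immediate early genes 6 were lower (8 adjusted over the list alone; fry adjusted p = 0.0299, exact permutation 0.0872). In total 3282 probes were higher and 4282 lower (325 and 10918 under median scaling), 5385 were called without the 9 old arrays, and 1445 were called with a random block for the number runs.

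Middle-aged minus young adult, the comparison of the groups most alike, had 6 called probes, 1 higher and 5 lower. Actb fell by 1.52 (SE 0.259, adjusted p = 0.0046), Pam, which amidates peptides, by 1.13 (SE 0.219), the ubiquitin ligase Huwe1 by 0.72 (SE 0.145) and the peptidase Prep by 0.68 (SE 0.144). Camera called 6 lists, in none of which a single member passed: skeletal muscle (mean -1.33, camera adjusted p = 6.62e-05), erythroid cells (-0.91), heat shock proteins (-0.32), hypoxia response (-0.28), MHC class I presentation (0.30) and interferon-stimulated genes (0.29). With an estimated correlation the adjusted p was 0.761 for heat shock proteins and 0.931 for the others, and fry and the permutation test called 0. Muscle transcripts varied within groups: Acta1 ran from 4.77 to 13.72 in young adult and from 4.58 to 9.47 in middle-aged tumours. Adjusted over the list alone, 1 hypoxia gene was lower. The members of lowest p were Myl1 (-2.44), Alas2 (-1.76), Hsp90aa1 (-0.44), Mxi1 (-0.99), B2m (0.47) and Bst2 (1.05), none of which passed. The count was 212 without the 9 old arrays, and 0 in limma with a random block for the number runs (28 at an unadjusted p under 0.05).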

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

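In this part the test of host age and the test by array numbers for the low arrays, the version of the lung test with the most abundant transcripts, its variant with silent genes and the test of their level were chosen only after the result was seen. Conditions added afterwards to tests that had been written down earlier are named where they apply.

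Old arrays 95 and 96 detected 729 probes that none of the other 52 arrays detected and that lie outside the filter. Over 17 lung epithelium genes, a list written after the arrays were seen, the lower of the pair lay above the highest of the other 52 arrays by a median of at least 4.42 (log2; many of the genes were not above background there), and 16 of the 17 genes were higher in both arrays than in any other. The count of 16 holds for the normalized values. In the raw signals Scgb3a1, Lamp3, Abca3 and Hopx were also lower in array 95 than in the highest of the other 52 arrays. Normalization as the whole source is argued against, since the raw signals differed by a median ratio of 2.66. Host age acting alike on every old tumour is argued against too, because 1 of the other 17 old arrays had a lung list mean above every younger array. Lung tissue in these samples may therefore be the source. Hopx, Rtkn2, Abca3 and Napsa were detected in all 52 other arrays, so the tumour expresses some genes of the list. Some transcripts of the other tumours, looked at after the arrays were seen, were lower in arrays 95 and 96. Prl2c3 was 6.07 and 5.13 there and at least 6.86 in the other 52 arrays. Mmp3 was 8.82 and 9.49 against at least 9.93, and Fn1 11.06 and 9.41 against at least 11.92. H19 was 10.10 and 7.57, and only array 96 lay below all other arrays (at least 7.97). How much of these 2 samples was tumour was not measured.

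In 8 old arrays, array 95 among them, fewer probes were detected than in any array of the other ages. The low arrays gathered in 1 stretch of numbers (7 of the 9 arrays numbered 73 to 98, 1 of the 10 with higher numbers, Fisher's exact p = 0.0055). This is in line with a technical batch and argues against host age acting alike on every old tumour as the whole cause, since all old arrays are of 1 age. For lung tissue at a lower share, 4 of the 7 low arrays other than 95 had a lung list mean above the other old arrays (array 96 left out), which met the criterion written beforehand. A condition added once this was known, that the genes of the list be detected there, was not met, so this count decides nothing. Of the 6 lung genes most abundant in arrays 95 and 96, 2 were detected in low arrays (Abca3 and Napsa, detected everywhere), and restricted afterwards to genes detected in at most 5 of the other 52 arrays it was 0 of 6; the first of these versions left the question open, and the last was picked with the outcome in view. The levels of these 6 silent genes argue only against a share of lung tissue near that of arrays 95 and 96. In arrays 95 and 96 they averaged 11.79 to 14.55 (log2). In the low arrays they reached at most 5.76, where none was detected, so that the smallest gap is at least 6.81. The low arrays were counted among the 52 when these genes were chosen, which favours low levels there. A small share of lung tissue is therefore not excluded. Array 96, with the highest lung list mean, detected 14608 probes and was not low.

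Interferon-stimulated genes were higher in old than in adolescent tumours. With the number run as a random block the list kept a camera p = 1.34e-05, which met the criterion written beforehand against the runs as the cause. Random regroupings showed this test to be too lenient, and a further condition added afterwards, a fry p under 0.05 with the same block, gave p = 0.0286 and an adjusted p = 0.63, so the case against the runs is weak and rests on an unadjusted p. List means were -0.55 and -0.21 in the adolescent runs and 0.39 and 0.12 in the old runs of more than 1 array. With 4 leukocyte list means as covariates 62.8% of the difference was left (0.39, SE 0.112), which met the criterion written beforehand against leukocytes. List means measure leukocytes with error, which can leave a difference even if leukocytes explain all of it. The dendritic cell list, 0.32 higher in old tumours, was not among the covariates. More leukocytes as the whole cause are therefore not excluded, and host age itself stays untested.

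Single arrays of the young adult and middle-aged groups stood apart from the rest of their group in 7 of 92 sets of list, signal and detection values and 16 of 252 sets of gene values; chance gives about 1 in 20. Young adult array 4 had the highest means for mesenchymal genes (0.66) and collagens and matrix proteins (1.27), the highest Srpx2 (8.37), and the lowest Usp18 (6.67) and Igf2 (5.45). Young adult array 2 had the highest mean for plasma cells and immunoglobulins (0.87), and array 9 the lowest Rhbdl1 (6.38). Young adult array 1 had the lowest Igdcc4 (5.52) and Mast4 (6.07) and the highest Psme2 (8.64). Middle-aged array 2 had the highest median raw signal (303), proteasome mean (0.34) and Ifi205 (8.26) and the lowest Hspa8 (12.91). Middle-aged array 5 had the highest skeletal muscle mean (0.55), Myl1 (8.91), Acta1 (9.47) and Pvalb (6.38). Middle-aged array 1 had the lowest Rhbdl1 (6.68) and Npm3 (7.70) and the highest Prf1 (10.87). Middle-aged array 3 had the lowest mean for p53 targets (-0.15), and array 6 the lowest Hbb-b1 (6.18).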

How the results depend on the processing

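The fits without 2 and without 9 old arrays, the block for number runs and the replicate block on the processed values were chosen after the arrays were seen; the cause of each change below was not tested unless stated. Without background correction middle-aged minus young adult had 25 probes and the lists of middle-aged minus adolescent numbered 3; with the processed values of the authors these were 23 and 3. Under median scaling the median log2 differences between groups ran from -0.64 to 0.35, against -0.07 to 0.02 before. It gave 4379 probes for middle-aged minus adolescent (4171 higher, 208 lower), 1299 for young adult minus adolescent (1174 higher, 125 lower) and 3 for middle-aged minus young adult, with old minus adolescent at 522 higher and 5815 lower. Lists then numbered 10, 5, 1, 12 and 6 for middle-aged minus adolescent, young adult minus adolescent, old minus young adult, middle-aged minus young adult and old minus middle-aged, and Cd274 in old minus middle-aged turned to -0.072, with the median over all probes at -0.64. With no filter the F called 20915. Old minus adolescent, young adult and middle-aged rose to 15285, 17532 and 15888, while contrasts without old tumours had 5 to 2922. Array weights gave 6294 for middle-aged minus adolescent, 4955 for young adult minus adolescent (1 list) and 1173 for middle-aged minus young adult. Bonferroni without moderation left 2368 for the F. With only 2 groups fitted the counts were 4546, 3830 and, for middle-aged minus young adult, 0 in limma (3000 at an unadjusted p under 0.05).

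With an estimated correlation camera called 0 lists in each contrast. Fry called 4 lists for old minus adolescent, 8 for young adult minus adolescent, 8 for old minus young adult, 0 for middle-aged minus young adult and 4 for old minus middle-aged. With the mean of all probes of a gene, 2 lists were called for middle-aged minus adolescent. Without 2 old arrays middle-aged minus young adult had 54 probes and old minus young adult 1 list. Without 9 arrays the counts were 3821 for old minus adolescent, 5093 for middle-aged minus adolescent, 4552 for young adult minus adolescent, 212 for middle-aged minus young adult, and 1 list for old minus young adult.

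With the number run as a random block 1690 probes were called by the F, 896 in old minus adolescent, 1333 in old minus young adult, 1445 in old minus middle-aged and 0 in limma in the others (unadjusted 1011, 649 and 28), with 2 lists for middle-aged minus adolescent. With that block and without 9 arrays these were 2164, 317, 2142 and 1523, then 722 for middle-aged minus adolescent, 335 for young adult minus adolescent and 0 for middle-aged minus young adult (unadjusted 662), with 1 list for old minus young adult. Of 59 pairs of arrays with the same replicate number 12 correlated above 0.1 (mean r -0.03), so the numbers do not pair the samples; a replicate block on the processed values gave 0 for middle-aged minus young adult (unadjusted 1931) and 2 and 0 lists for middle-aged and young adult minus adolescent.

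Leaving out 1 array gave 0 to 221 probes for middle-aged minus young adult. The count was 22, 19, 1, 221, 27, 1, 2, 1 and 1 without young adult arrays 7, 5, 9, 1, 3, 6, 8, 10 and 2. It was 0, 1, 1, 2, 2, 218 and 10 without middle-aged arrays 2, 3, 4, 5, 6, 1 and 7, and 20 and 10 without old arrays 96 and 98. Lists ran from 2 to 7 for middle-aged minus adolescent, 1 to 7 for young adult minus adolescent and 3 to 9 for middle-aged minus young adult. The other probe counts stayed within 1.5 times their value, and named genes were not refitted for single arrays. In the 8 alternatives run for them (median scaling, no background correction, processed values, array weights, without 2 or 9 arrays, number runs, replicate block), all but Cd274 kept their sign where they had been called, but 68.8% of these results were no longer called with the number runs, 15.3% with median scaling, 11.5% with the replicate block, 9.6% and 3.8% without 9 and 2 arrays, 4.5% each without background correction and with the processed values, and 3.2% with array weights. Calls of single lists were lost, with the adjusted p in brackets, on leaving out the arrays named here by group and order. Middle-aged minus adolescent, MHC class II presentation: adolescent 1 (0.0571), 2 (0.0844), 5 (0.0526), 7 (0.0663), 9 (0.0673), 13 (0.0648), 14 (0.0694), 15 (0.0584), 18 (0.0646); middle-aged 4 (0.285), 5 (0.0706), 6 (0.187). Middle-aged minus adolescent, complement: adolescent 1 (0.0504), 2 (0.0575), 8 (0.0551), 15 (0.0532), 18 (0.0646); middle-aged 3 (0.0554), 4 (0.155), 5 (0.0706), 6 (0.0588). Middle-aged minus adolescent, cytosolic ribosomal proteins: adolescent 8 (0.0551), 18 (0.0516); middle-aged 2 (0.288), 5 (0.109). Young adult minus adolescent, immediate early genes: young adult 8 (0.0986), 2 (0.0595). Middle-aged minus young adult, hypoxia response: young adult 7 (0.068), 4 (0.0869), 9 (0.0583), 2 (0.0827); middle-aged 3 (0.175), 4 (0.0968). Middle-aged minus young adult, interferon-stimulated genes: young adult 7 (0.068), 4 (0.092); middle-aged 2 (0.0522), 4 (0.247), 5 (0.0559), 6 (0.0674). Middle-aged minus young adult, MHC class I presentation: young adult 7 (0.068); middle-aged 4 (0.248), 6 (0.0788). Middle-aged minus young adult, erythroid cells: young adult 2 (0.0728); middle-aged 6 (0.0506).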

Other observations

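In this part the test of Xist against Y-linked transcripts and the permutation test of list means were chosen only after the data were seen. Further gene groups differed by the permutation test without being called by camera. In old minus adolescent tumours Schwann cell and nerve genes averaged 0.31 (permutation adjusted p = 0.026), but 0.039 without the 9 old arrays. This mean was 0.19 without background correction and 0.20 in the processed values of the authors. It was 0.008 under median scaling, where the median over all probes was -0.28. In middle-aged minus adolescent tumours endothelial genes averaged -0.43, p53 targets 0.24, dendritic cell genes 0.40 and proteasome genes 0.11 (exact permutation adjusted p = 0.0279 for each). Under median scaling these were -0.02, 0.54, 0.68 and 0.26, with the median over all probes at 0.35. The proteasome difference leans on middle-aged array 2, whose list mean was 0.34, with the next highest of the group at 0.09. In young adult minus adolescent tumours the platelet and megakaryocyte list averaged 0.82, p53 targets 0.23, immune checkpoints 0.23 and the TGF-beta pathway 0.20 (permutation adjusted p = 0.0102 for each), dendritic cell genes 0.32 (0.0283), and DNA double-strand break repair -0.14 and cytosolic ribosomal proteins -0.079 (0.048 for each); under median scaling the last 2 were -0.02 and -0.23, with the median over all probes at 0.09. In old minus young adult tumours the TGF-beta pathway averaged -0.22, oxidative phosphorylation -0.17 and heat shock proteins -0.26 (permutation adjusted p = 0.0282 for each), and immediate early genes -0.45 (0.0406). Without the 9 old arrays these differences were -0.14, -0.078, -0.19 and -0.35 (adjusted p = 0.183, 0.183, 0.25 and 0.183), with fewer arrays compared. Other lists passed only without these arrays: immune checkpoints in old minus adolescent (0.20, adjusted p = 0.0088), p53 targets (-0.23, 0.0095), break repair (0.13, 0.0372), ribosomal proteins (0.086, 0.0162) and housekeeping controls (0.14, 0.0162) in old minus young adult, and platelets (-0.81, 0.0294), p53 targets (-0.25, 0.0445) and proteasome genes (-0.12, 0.0445) in old minus middle-aged. The housekeeping list holds control genes, so its passing warns that differences of this size may not be particular to the lists named. The permutation test also took no account of the number runs. Within runs the arrays correlated at 0.31, or 0.15 without the 9 old arrays. Muscle transcripts were abundant in single tumours: Ckm reached 14.43 in an adolescent and 11.22 in a young adult array, against group medians of 4.62 and 4.64. The liver list, added after the arrays were seen, averaged 0.39 in adolescent and -0.33 in old tumours; Alb was detected in 0 of 54 arrays.

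Random regroupings of the arrays into groups of the same sizes tested whether the counts could arise by chance. Among 100 groupings, the real one included, 1 gave as many probes as the F over 4 groups (10403, highest other 2200), old minus adolescent (6963, highest other 1929), middle-aged minus adolescent (2798, highest other 7), young adult minus adolescent (2553, highest other 146), old minus young adult (7931, highest other 2850) and old minus middle-aged (7564, highest other 5872). For middle-aged minus young adult it was 2 (6 probes, highest other 41). Chance is argued against for the probe counts that no other grouping reached, though not a batch that follows the groups. For middle-aged minus young adult the 2 of 100 met the criterion written beforehand against chance. Its count is small and unstable, however: it ran from 0 to 221 depending on which 1 array was left out. Leaving out arrays does not test chance, but for so unstable a count chance is not taken as excluded. A regrouping of the middle-aged and young adult arrays that called 41 probes, several times the real count, may point to a structure among these samples, which was not tested. For the lists called by camera, as many were found in 94, 81, 92, 100, 71 and 100 of 100 groupings for old minus adolescent, middle-aged minus adolescent, young adult minus adolescent, old minus young adult, middle-aged minus young adult and old minus middle-aged. The real numbers were 2, 5, 2, 0, 6 and 0, and the highest others 22, 22, 22, 19, 21 and 21. Chance cannot be excluded for any of the numbers of lists above 0. Where the real number was 0, every grouping reaches it, so the regroupings tested nothing there.

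A hypothesis was that Xist comes from the implanted cells and the Y-linked transcripts Ddx3y and Eif2s3y from the male host. It predicts that Xist falls as these rise within a group. In adolescent tumours Pearson's r was -0.33 (permutation p = 0.182, adjusted 0.364 over 4 relations; Spearman's rho -0.24, p = 0.332; r = -0.22 without the 2 farthest arrays). In old tumours r was -0.70 (permutation p = 0.0073, adjusted 0.0294; rho 0.14, p = 0.569), but 0.51 without the 2 farthest arrays, so that relation rests on those samples. Those 2 are old arrays 95 and 96, which carried lung transcripts. Ddx3y was 12.23 and 12.59 there, against at most 10.62 in the other old arrays. Xist was 9.07 and 6.51 there, against at least 9.94 in the other old arrays. The prediction for adolescent and old tumours alike was not met, since r in adolescent tumours was below 0 without passing. By this test the hypothesis is therefore neither upheld nor ruled out. Xist ran only from 10.11 to 11.20 in adolescent tumours, which left the correlation little range to show a fall. Apart from the correlations, Xist was detected in all 54 arrays although every host was male.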
